A study of Drosophila melanogaster with 2 samples.

How the data were processed

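The data are one peak list from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Polycomb-like (Pcl) in whole embryos of Drosophila melanogaster collected 0 to 8 h after egg laying. Pcl is a PHD-finger protein that associates with Polycomb repressive complex PRC2, the enzyme complex that methylates lysine 27 of histone H3. Per the labels' protocols, embryos were crosslinked with formaldehyde, the chromatin was sonicated and precipitated with an antibody against Pcl, and input DNA from the same kind of chromatin served as the control. The title of the ChIP sample names replicates 1, 2 and 3 together, so the list is for pooled or combined replicates; how they were combined is not given in the sources used here. The input sample, labelled as number 1, has no peak list of its own and was not analysed here.

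The authors' processing is known only in outline. Per the submitters' processing notes, Bowtie was used and the genome build was BDGP5 (Release 5 of the Drosophila genome); no version is given for Bowtie. Per the file headers, the peaks were called with MACS, whose version and settings are not given in the sources used here. Each line of the deposited list holds a sequence name, a start, an end, a peak name and the deposited score, which is the peak caller's own value for that peak and not a measured occupancy. The scale of this score is not stated in the file. The lowest deposited score is 50.01, which shows a cut-off close to that value. Scores were used only within this list, to rank, describe and compare peaks. A check of the peak density on X also scaled scores by a factor, which assumes a proportional scale that the file does not state. The list gives no read counts, fold enrichments, summits or false discovery rates, so the sequencing depth behind each peak is unknown and no replicate error can be attached to any value.

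Starts were converted to 1-based positions. Peaks on one sequence with gaps under 10 kb were grouped into clusters, because neighbouring peaks are not independent observations. The share of clusters on each arm was given with a 95% exact (Clopper-Pearson) binomial interval, which covers counting error only. The median width of all peaks was given an exact binomial interval from the ordered widths, which treats all peaks as independent and so is likely too narrow. The distance between the centres of neighbouring peaks was compared with 100000 uniform placements of the same number of peaks between the first and the last peak of each sequence, two-sided. The number of clusters and the size of the largest cluster were compared with 10000 such placements. Assembled arm lengths were not used here, so densities are per Mb of the span from the first to the last peak of an arm. Peak density on X and on the autosomal arms was compared by a two-sided permutation test of 1 Mb bins (100000 permutations) with a bootstrap interval over bins (2000 draws). Neighbouring bins are not independent, and these p-values describe variation along the genome in this one list, not variation between embryos or libraries. Scores of clustered and lone peaks, and scores and widths of X and autosomal clusters, were compared by a permutation test of medians (100000 permutations, two-sided), with each cluster represented by its first peak in map order so that every cluster counted once; the widths of clustered and lone peaks were not tested. Membership of the highest-scoring peaks in the largest cluster, and on X, was compared by Fisher's exact test, two-sided.

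The gene lists, annotation classes, distances to transcription start sites and sequence motifs planned before the data were examined were not evaluated, since the only gene table used here is of Release 6 and coordinates were not converted between builds. No peak was therefore assigned to a gene. Under the rule fixed in advance for lists without an annotation, the regions named in the results are the 20 peaks with the highest score and the 5 longest clusters. The comparison of peak numbers, widths, arm shares and neighbour distances was planned in advance. The comparisons of clustered with lone peaks, of X with autosomal density and of the highest-scoring peaks were added after the data were seen.

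Alternatives planned in advance were the 1228 peaks with the highest scores, joining of peaks with gaps under 1 kb, restriction to the arms 2L, 2R, 3L, 3R, X and 4, and cluster gaps of 1 kb and 50 kb. Alternatives chosen after the data were seen were score minimums of 60 and 100, joining of gaps under 5 kb, placement within 1 Mb bins, omission of the largest cluster, omission of 3R, and other numbers of top peaks. The placement and median tests were tested on simulated data. In 50 simulated lists of 2414 uniformly placed peaks, the placement test gave p under 0.05 in 3. In 50 lists in which some of the peaks were set beside others, it did so in all 50. The median test gave p under 0.05 in 3 of 50 simulated sets of 1453 values without a difference and in 50 of 50 with one. The simulated difference was larger than the observed one, so how often a difference of the observed size would be found was not measured. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.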

Results

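The binding of Pcl, a partner of the histone H3 lysine 27 methyltransferase complex PRC2, was mapped by ChIP-seq in whole fly embryos of 0 to 8 h. The samples comprised one ChIP group, whose label combines 3 replicates, and one input control. A single list of 2457 peaks represents the ChIP group, and no replicate error could be computed. The comparisons therefore concern where in the genome Pcl peaks lay and how peaks of different regions ranked in this list. All positions are on build BDGP5.

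Pcl peaks were short and few relative to the genome. The median peak width was 830 bp, with quartiles of 713 and 1052 bp and a range of 267 to 4459 bp. All peaks together covered 2.35 Mb. The authors' peak score had a median of 73.6 and quartiles of 59.5 and 105, whereas the highest score was 2377.39. Scores of at least 200 were reached by 183 peaks and scores of at least 500 by 50 peaks. At the other end, 640 peaks scored below 60, close to the lowest score in the list of 50.01, so the total number depends on the authors' cut-off. Wider peaks had higher scores (Spearman's rho = 0.67 across the 2457 peaks, which are not independent replicates).

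Pcl peaks lay on all of the major chromosome arms, with the highest number on 3R and a low number on X. The arm 3R carried 791 peaks, 2R 537, 3L 508, 2L 388 and X 190, and chromosome 4 carried 2. Over the span between the first and the last peak, 3R held 28.5 peaks per Mb, 2R 27.7, 3L 22.2, 2L 17.8 and X 9.14. The lead of 3R in density rested on 1 region: without its largest cluster, 3R held 684 peaks or 24.6 per Mb, below 2R. After neighbouring peaks with gaps under 10 kb were joined, 1453 clusters remained. Of these, 27.3% (95% exact interval 24.98 to 29.62) were on 3R, 23.0% (20.8 to 25.2) on 3L, 21.1% (19.1 to 23.3) on 2R, 18.2% (16.2 to 20.2) on 2L and 8.19% (6.83 to 9.72) on X. Per Mb of span, 2R held 15.8 clusters, 3L 14.6, 3R 14.3, 2L 12.1 and X 5.73. The 2 peaks of chromosome 4 formed 1 cluster and had scores of 106 and 51.4. A further 41 peaks were on sequences outside these arms.

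Peak density on X was 0.38 times that on the 4 large autosomal arms combined, 9.14 against 24.2 peaks per Mb. The 95% bootstrap interval of this ratio over 1 Mb bins was 0.27 to 0.49. Bins of X held 9.05 ± 5.46 peaks (SD over 20 bins), and autosomal bins held 23.9 ± 15.9 peaks (SD over 89 bins; permutation test of bins, p = 0.00018). In score and width X lay nearer to the autosomal arms. Peaks scoring below 50.01 are missing from every arm, so like median scores do not show that X peaks were as strong as autosomal ones. The first peaks of X clusters had a median score of 69.7 against 68.9 on the autosomal arms (difference 0.84, permutation p = 0.83, 119 X clusters against 1301 autosomal clusters). Their median width was 749 bp against 803 bp, a difference of -54 bp for X minus autosomal arms (permutation p = 0.025). X carried 4 of the 20 highest-scoring peaks of the arms, where its share of all arm peaks gives 1.57 (Fisher's exact test, p = 0.066), 6 of the top 50 (3.93 from its share, p = 0.28) and 11 of the top 100 (7.86 from its share, p = 0.25); none of these counts passed the test.

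**Figure D1:**
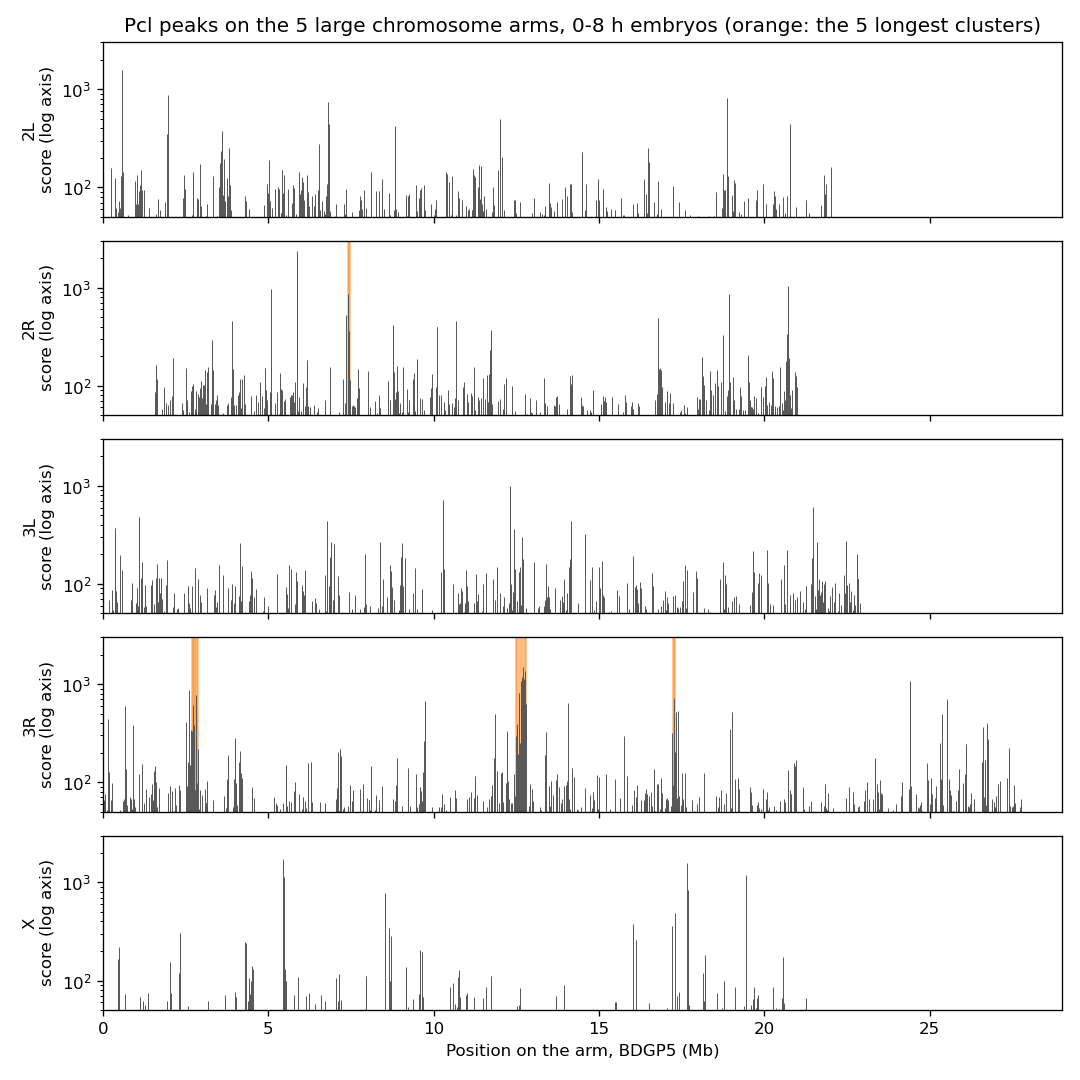
Score of every Pcl peak (vertical lines, log axis) against its position in Mb on the arms 2L, 2R, 3L, 3R and X, with the 5 longest clusters in orange. Peaks are sparser on X (190) than on the autosomal arms, and 4 of the 5 longest clusters lie on 3R.

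Pcl peaks were grouped along the chromosomes. The median distance between the centres of neighbouring peaks was 17.8 kb, against 30.6 kb for uniform placement (95% of placements 29.3 to 31.8 kb). The observed distance was thus 0.58 times the expected one (permutation p = 2.0e-05, the smallest that the 100000 placements can give). Peaks were closer than uniform placement on each of the 5 large arms, with a ratio of 0.61 on 2L, 0.62 on 2R, 0.72 on 3L, 0.45 on 3R and 0.25 on X (each with a Benjamini-Hochberg adjusted permutation p of 2.0e-05 over the 5 arms). The observed median distance was 10.96 kb on 3R, 15.7 kb on 2R, 19.1 kb on X, 22.7 kb on 3L and 24.0 kb on 2L. The expected distance was 76.4 kb on X, against 24.4 to 39.1 kb on the other large arms. The lowest ratio, on X, thus came with the widest expected distance and not with the shortest observed one. The 1453 clusters compare with 1908 under uniform placement (95% of placements 1873 to 1943). In all, 1448 peaks (58.9%) shared a cluster with another peak, and 1009 stood alone. Clusters of at least 5 peaks numbered 51, and clusters of at least 10 peaks numbered 9. The counts and distances for the whole list include sequences outside the arms, and the 9 include a cluster of 10 peaks on unplaced sequence. On the arms alone the ratio of observed to expected distance was also 0.58.

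The largest cluster lay on 3R from 12487002 to 12805868 and held 107 peaks. This stretch of 319 kb contained 4.35% of all peaks of the list and 13.5% of those on 3R. Peaks covered 40.2% of its length, with a median gap of 782 bp between them. In 10000 uniform placements the most populated cluster held a median of 6 and at most 13 peaks. The next largest cluster of the observed list held 20. The placements treat every peak as a separate site. In the largest cluster 63 gaps were under 1 kb, so splitting of broader regions by the peak caller may have raised its count. This was not tested for the cluster.

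High scores were concentrated in this region of 3R. It contained 15 of the 50 peaks with a score of at least 500. It also contained 6 of the 20 highest-scoring peaks, where its share of all peaks gives 0.871 (Fisher's exact test, odds ratio 9.91, p = 0.00014). Peaks of one region are not independent. The region was also picked from this same list as its most populated cluster, and other clustered peaks scored higher than lone peaks too. The p-value therefore does not measure how unusual this count is for a region so picked. These 6 peaks were at 12709403 to 12713861 (score 1496), 12773971 to 12777324 (1361), 12672368 to 12673801 (1178), 12757818 to 12760963 (1170), 12724911 to 12726892 (1132) and 12634977 to 12638214 (1077). Within the region the scores were uneven. The first 102 kb held 30 peaks, the highest of which scored 389.45. The first peak with a score of at least 500 started at 12588877. The part of the region before its midpoint held 48 peaks with a median score of 83.0, of which 2 scored at least 500. The part after it held 59 peaks with a median score of 156, of which 13 did.

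**Figure D2:**
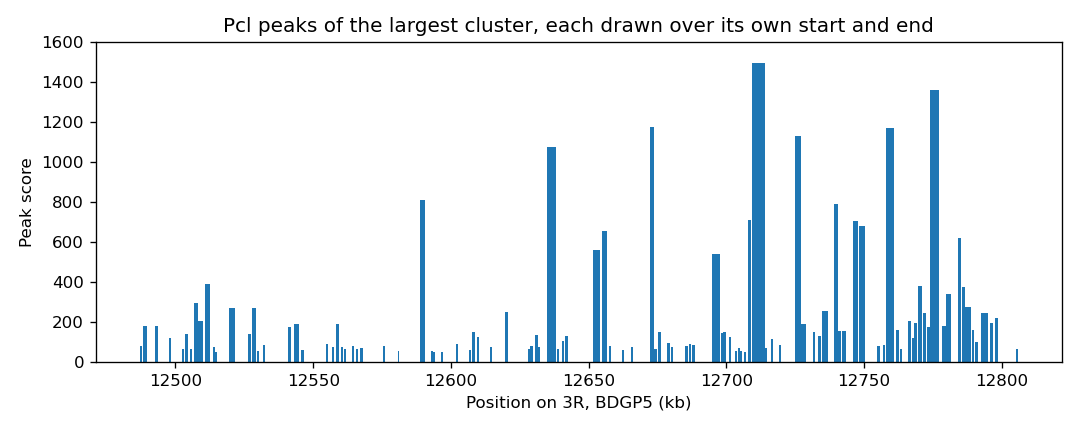
Score of the 107 Pcl peaks of the largest cluster (bars, linear axis from 0) against position in kb on 3R, each bar spanning the peak from its start to its end. The first 30 peaks stay at or below a score of 389.45, and the 6 highest peaks score from 1077 to 1496.

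The other long clusters were between 58.6 and 92.0 kb long, and 3 of these 4 were also on 3R. A pair of them lay 17.6 kb apart. The first of the pair ran from 2690019 to 2762802 with 19 peaks, a peak coverage of 30.2% and a highest score of 614 at 2728712 to 2731318. The second ran from 2780420 to 2872463 with 20 peaks, a coverage of 22.1% and a highest score of 769 at 2826119 to 2827398. A further cluster of 3R ran from 17242299 to 17300879 with 16 peaks, a coverage of 29.4% and a highest score of 724. On 2R, the region from 7402016 to 7484702 held 17 peaks with a coverage of 26.7%, and its highest peak, at 7413621 to 7416716, scored 850. The median gap between peaks was 1441 bp and 4706 bp in the pair on 3R, 2265 bp in the third of these 3R clusters and 3327 bp on 2R. Each of these gaps exceeded the 782 bp of the largest cluster.

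The peak with the highest score of the whole list was on 2R at 5864566 to 5869013, with a score of 2377.39 and a width of 4448 bp. It belonged to a cluster of 5 peaks. The second was on X at 5452394 to 5456010 (score 1736), and X also carried the peaks at 17661099 to 17663824 (1561), 19437393 to 19441740 (1203) and 5487675 to 5489359 (1140). On 2L the highest peaks were at 592102 to 595955 (1558) and 1969893 to 1973690 (872). On 3R outside the largest cluster, the peak at 24407918 to 24412282 scored 1079. The remaining arm peaks among the top 20 were on 2R at 20700376 to 20703439 (1047), 5081994 to 5083831 (964) and 18933245 to 18936024 (868), and on 3L at 12321255 to 12323745 (989). The other 2 of the top 20 lay outside the arms, 1 on the unplaced sequence U and 1 on the mitochondrial sequence. The median width of the 20 peaks was 3105 bp, and 19 of them shared a cluster with at least 1 other peak.

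Clustered peaks scored higher than lone peaks. With each cluster represented by its first peak in map order, the median score was 76.4 (quartiles 60.7 and 108) for 444 clusters of at least 2 peaks, and 67.4 (quartiles 57.2 and 87.1) for 1009 lone peaks. The difference of 8.99 was larger than label permutation gave (p = 1.0e-05, the smallest that 100000 permutations can give). The median widths were 852.5 bp and 777 bp, a difference that was not tested. With a gap of 50 kb in place of 10 kb the difference was 2.53 and did not pass the test (permutation p = 0.21), whereas it was 20.8 with a gap of 1 kb (permutation p = 1.0e-05). A peak counts as clustered only if a neighbour also passed the authors' cut-off. Splitting of strong regions into several peaks would also give higher scores in clusters, and the test cannot tell this apart.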

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

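Both explanations weighed here for the grouping of peaks, and the one for X, were tested only after the grouping and the counts per arm had been seen. What each would predict was written before its own test was run.

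Signals outside the chromosome arms compared in the results were present in 41 peaks on the unplaced sequences U and Uextra, on 2RHet and on the mitochondrial sequence. Uextra held 27 of them, U 11, 2RHet 2 and the mitochondrial sequence 1. On U, 10 peaks lay within 16.9 kb, from 5288268 to 5305143, and the highest of them scored 1659.23, the third highest value of the list. The mitochondrial peak, at 17005 to 17605, scored 1055.46 and was 601 bp wide. Scores of at least 200 were reached by 15 of the 41 peaks (36.6%) against 168 of 2416 peaks on the arms (6.95%). The 10 peaks of the stretch on U had a median score of 260, so part of these 15 came from that stretch. Copy number and mapping of the sequences outside the arms were not examined, so high scores there do not by themselves show Pcl binding. At equal score the peaks outside the arms were narrower. In 40 of 41 cases the width was below the median of the 20 arm peaks nearest in score, with a median ratio of 0.38 and a range of 0.20 to 1.00. One peak of 2RHet is listed with a 1-based start of -104, before the first base of its sequence.

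The grouping of peaks was weighed against 2 technical explanations. If the peak caller had split broad regions into several peaks, joining peaks with gaps under 5 kb would bring the neighbour distance up to that of uniform placement. After joining, the ratio of observed to expected distance was 0.83, still below the placements (permutation p = 2.0e-05), although joining by itself removes all short distances. This argues against splitting at gaps under 5 kb as the whole cause. The rise from 0.58 to 0.83 leaves open that part of the grouping comes from it. If variation of peak density over megabases, such as gaps of the assembly, were the cause, placing each peak at random within its own 1 Mb bin would remove the pattern, but the ratio was 0.66 (permutation p = 2.0e-05). Splitting at gaps wider than 5 kb and the 2 explanations acting together were not tested. Local structure below 1 Mb, including the spacing of genes and of mappable sequence, was not tested either.

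The low number of peaks on X was weighed against one technical explanation. In a collection with as many males as females, X is present at 0.75 times the copy number of autosomes, which lowers the reads available for each X peak. The labels do not give the sex of the embryos. If copy number scaled all X scores by one factor, the factor that gives the X density would include 0.75, but it was 0.60 (95% bootstrap interval 0.50 to 0.68), so this part of the prediction failed. Scaling of every score by 0.75 would thus not give the X density. This result bears on copy number only if scores follow read number in proportion. At the fitted factor, the density of X peaks scoring at least 100 was 1.30 times the predicted one (interval 0.90 to 1.82), which tests a single factor of any size and says nothing about 0.75. Only an interval of this ratio excluding 1 had been set as counting against the explanation, so the test could not decide. How the score changes with read number is not known from the list, so copy number cannot be told apart from other causes as a part of the difference. No biological explanation was tested.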

How the results depend on the processing

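No tested difference or ratio changed direction, but the order of the arms by share of clusters changed with the cluster gap. At 10 kb 3L held 23.0% and 2R 21.1%, whereas at 1 kb 3L held 21.3% and 2R 22.3%. At 50 kb 2L held 19.5% and 2R 18.7%, against 18.2% and 21.1% at 10 kb. The stricter list held the 1228 peaks with the highest scores, and with a minimum score of 100 it held 671, by construction of these lists. The median width of 830 bp (95% exact interval 816 to 843) became 1007.5 bp in the stricter list. It was 912 bp with a minimum score of 60 and 1173 bp with a minimum of 100, and so depends on the score cut-off. Since wider peaks had higher scores, this rise follows from how those lists were made. After joining gaps under 1 kb the median was 845 bp, just outside an interval that treats all peaks as independent. A cluster gap of 50 kb moved the share of clusters to 18.7% on 2R, 24.9% on 3R and 10.6% on X, and a gap of 1 kb moved that on 3R to 30.2%, each outside the exact interval of the share at 10 kb; X kept the lowest share of the 5 large arms. The higher score of clustered peaks did not pass the test at a gap of 50 kb (2.53, permutation p = 0.21); the cause was not tested. The other 33 recomputed values kept their direction and side of the threshold or, where no test was run, stayed within 1.5 times for numbers of peaks and the exact interval for median widths and arm shares. The ratio of neighbour distances ranged from 0.42 in that stricter list to 0.83 after joining gaps under 5 kb, and was 0.60 without the largest cluster. The X to autosome density ratio ranged from 0.37 to 0.41, including 0.40 without the largest cluster and 0.41 without 3R. The odds ratio for top peaks in the largest cluster was 6.05 for the top 100 by score and 5.67 for the top 20 by width. Omission of single replicates could not be run, and no paired analysis was possible because the list combines the replicates. The planned analyses of transcription start sites, annotation classes, gene lists, scores by gene list and motifs were not run, since no Release 5 annotation or sequence was used here. Without read counts, peaks below the authors' cut-off cannot be told from unbound sequence.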

Other observations

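Position on the chromosome and score were related beyond the largest cluster, in a relation examined after the grouping of peaks had been seen. The hypothesis was that peaks of one cluster share a local level of enrichment. Across 995 pairs of neighbouring arm peaks with gaps under 10 kb, the scores had a Spearman's rho of 0.19 (adjusted permutation p = 4.0e-05). Without the largest cluster rho was 0.16 over 889 pairs (adjusted permutation p = 4.0e-05), and without the 5 longest clusters it was 0.16 over 821 pairs. For gaps of 10 to 50 kb rho was 0.06 over 785 pairs (adjusted permutation p = 0.14), and for gaps over 50 kb it was -0.02 over 630 pairs (adjusted permutation p = 0.59). The p-values are adjusted over the 6 relations computed, and pairs of peaks are not independent replicates. The values are consistent with a shared local level, but the relation is weak, and splitting of one enriched region into neighbouring peaks would give a like relation.

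As background and not as a result, the published Release 5 map places the bithorax complex of homeotic genes in the part of 3R that holds the largest cluster, and the Antennapedia complex in the part that holds the pair of long clusters near the start of 3R. Both complexes are textbook targets of Polycomb regulation. These placements were not looked up or tested here, since no Release 5 annotation was used, and the remaining peaks carry no gene assignment.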
